A study of Mus musculus with 4 samples.

How the data were processed

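RNA was measured in 4 libraries of C57BL/6N mouse embryos collected at the late 2-cell stage. The 2 control libraries and the 2 Uqcc3 siRNA libraries were grouped by the treatment label of each sample. Per the labels' protocols, the siRNA against Uqcc3 was injected at 5 µM and at 8 hpi as the labels write it, and control embryos received a negative-control siRNA at the same dose and time. The treatment label of the controls reads "none" and the design text speaks of normal embryos, so the sources differ on whether the controls were injected. Full-length cDNA was made with an oligo(dT) primer and a single-cell amplification kit, and sequenced in pairs, per the labels' protocols. The number of embryos in a library is not given in the sources used here. The labels carry no replicate numbers, so replicates were numbered in accession order. The end of the sample titles differs between the groups. If it marks a batch, the batch and the group cannot be told apart. Nothing in the labels says that replicates came from separate mice or injection days, so p-values of single genes measure the spread between these libraries, which may be technical.

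The authors deposited 1 table of FPKM values per library (fragments scaled to transcript length and library size), with a lower and an upper bound for each gene, per the file headers. The submitters' processing notes name Trim Galore 0.6.5, STAR 2.7.3a, SAMtools 1.7, Cufflinks 2.2.1 and Cuffdiff 2.2.1 and the build mm10. The release of the gene annotation is not given in the sources used here. Each table held 47511 rows and 47445 gene identifiers. The rows of the 50 identifiers with several rows were summed. Of the identifiers, 99.1% matched GENCODE M21 without their version, and that release gave transcript length, GC content and the gene model of Uqcc3. Length and GC content are those of the longest annotated transcript of a gene, coding or not. It need not be the transcript expressed in these embryos.

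No counts were used. The upper bound lay 2 errors above the FPKM value, and an error equal to the value marked genes with 1 fragment. The number of fragments behind a value was therefore taken as the square of 2 times FPKM over the distance to the upper bound. Of genes with 1 annotated transcript and up to 30 implied fragments, 68.1% to 77.0% came out whole within 0.05 in the 4 libraries. The implied totals were about 16500000 and 18700000 fragments in control replicates 1 and 2, and 11500000 and 11700000 in siRNA replicates 1 and 2. These totals describe depth and entered no main test. They cover counting error only, since amplified fragments are not independent molecules.

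Genes with at least 1 FPKM in at least 2 of the 4 libraries were tested, and 2 genes whose estimate the authors' program marked as failed were left out. This left 12390 genes. The test was limma 3.58.1 (R 4.3.3) on log2(FPKM + 1) with an abundance trend in the prior variance, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this scale, which understates changes of low genes. With 2 libraries against 2, an exact permutation test cannot give a two-sided p below 0.333. Gene lists were tested with camera of limma at its preset correlation between genes of 0.01, over the 25 lists with at least 5 tested members. At this preset the test weighs the members of a list against the other genes, as do the random lists described below. Genes stand in for replicates there, so small p-values of lists do not show that a shift would recur in other libraries. The 26 lists, the tests and the rule for named genes were fixed before the data were examined. The lists cover complex III subunits and assembly factors, complex I subunits, complex IV and V subunits, mitochondrially encoded mRNAs, mitochondrial ribosomal proteins, mitochondrial proteostasis, the pyruvate and TCA cycle, glycolysis and lactate, antioxidants, 2-cell-specific genes, maternal oocyte transcripts, and cleavage-stage and pluripotency transcription factors. They also cover ribosome biogenesis, cytosolic ribosomal proteins, the proteasome, spliceosome core factors, mitosis, DNA replication, the integrated stress response, p53 targets, interferon-stimulated genes and RNA interference. The remaining lists hold markers of cumulus and granulosa cells, sperm, blood and blastocyst lineages. A list's offset is its median log2 difference minus the median of all tested genes.

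The text names Uqcc3, the 12 genes per direction with the largest change among those past the threshold with a mean of at least 5 FPKM in the higher group, and the 4 members of each list with the smallest unadjusted p. Where fewer than 12 passed, the direction was filled by smallest unadjusted p, leaving out predicted-gene names. Of the genes this rule gives, 2 are not reported here. The test was run on simulated data with 200 changed genes. With the spread of the 4 libraries it recovered 5% of 100 genes changed 4-fold and 71% of 100 genes changed 16-fold among 12390 genes. With the spread between the 2 controls it recovered 45% and 99%.

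Alternatives fixed at the same time were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, rescaling to TPM, median-of-ratios scaling, quantile normalization, limma without the trend and with a robust prior, cyclic loess on abundance, a loess correction on transcript length, a replicate block, keeping genes marked as failed, and leaving out each library. For lists they were an estimated correlation, fry, and 10000 random lists matched on mean expression. With an estimated correlation camera rests on the 2 residual degrees of freedom, and on fewer when a library is left out. Few lists could pass that version whatever their shift. Library weights, a correction on length and GC content (alone and without siRNA replicate 2), a minimum of 10 implied fragments, a minimum of 200 in both controls (lists of siRNA replicate 1), an estimated correlation in the fits of 3 libraries, and random lists matched on expression and length were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for reading and drawing.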

Results

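The series asked what loss of Uqcc3 does in embryos at the time the zygotic genome becomes active. Uqcc3 encodes an assembly factor of complex III of the mitochondrial respiratory chain. Polyadenylated RNA was profiled in 2 control libraries and 2 libraries of embryos injected with siRNA against Uqcc3, all at the late 2-cell stage.

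The implied depth was about 16500000 and 18700000 fragments in control replicates 1 and 2 and 11500000 and 11700000 in siRNA replicates 1 and 2. Genes with at least 1 FPKM numbered 12202 and 11818 in the controls, 12073 in siRNA replicate 1 and 9771 in siRNA replicate 2. Across genes, which are not independent replicates, log2 values of siRNA replicate 2 correlated with those of the other libraries at 0.624 to 0.651, and the highest correlation of each other library was 0.872 or 0.875. Mitochondrially encoded mRNAs made up 9.98% and 11.8% of summed FPKM in the controls, 17.9% in siRNA replicate 1 and 3.41% in siRNA replicate 2. The ribosomal RNA gene Rn18s-rs5 stood at 1023, 183, 566 and 14506 FPKM in control replicates 1 and 2 and siRNA replicates 1 and 2. Of 2476 genes at 20 FPKM or more in the other 3 libraries, 112 lay under 1 FPKM in siRNA replicate 2. The same count was 2 of 1828 and 2 of 1861 in the controls and 0 of 2032 in siRNA replicate 1.

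Uqcc3 transcript was lower in both siRNA libraries than in both controls. Uqcc3 (ENSMUSG00000071654.5) lies on chromosome 19 from 8880016 to 8880933 in mm10, and GENCODE M21 gives it 2 exons on the minus strand. It stood at 147 and 211 FPKM in control replicates 1 and 2 and at 23.7 and 19.8 FPKM in siRNA replicates 1 and 2, with 1820, 2858, 190 and 169 implied fragments. The mean was 179 ± 44.9 FPKM (SD, n = 2) in controls and 21.7 ± 2.73 FPKM (SD, n = 2) with siRNA, 12.1% of the control mean. Its log2 fold change was -2.97 (SE 0.63), and it did not pass the threshold over all genes in limma (adjusted p = 0.745). Over 21 alternatives it passed only when siRNA replicate 1 was left out (limma log2 fold change -3.09), which sets siRNA replicate 2 alone against the controls. Uqcc3 ranked 430 by p in that fit, against 4 in the main fit, so the pass was not particular to the target. Short genes in general were lower in siRNA replicate 2, as described below.

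**Figure D1:**
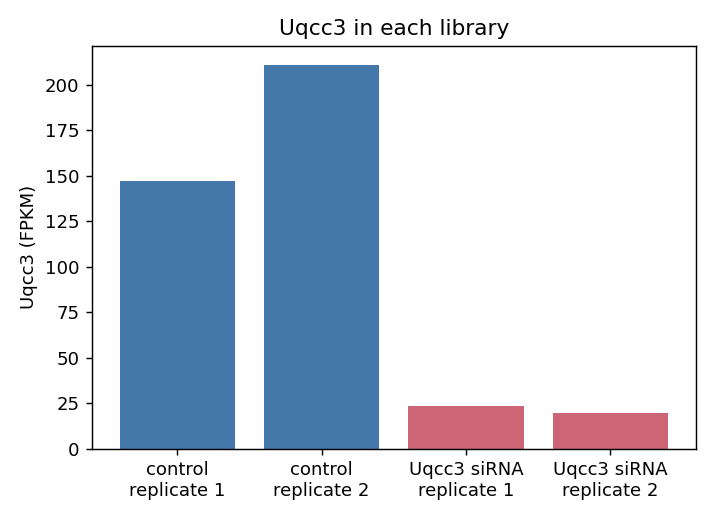
Uqcc3 in each library, with FPKM on the vertical axis and 1 bar per library (blue, control, and red, Uqcc3 siRNA). The controls stand at 147 and 211 FPKM and the siRNA libraries at 23.7 and 19.8 FPKM.

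No gene passed an adjusted p of 0.05 in limma among the 12390 tested (smallest adjusted p = 0.564). In limma, 738 genes had an unadjusted p under 0.05, where chance gives 620. Of these, 646 were lower and 92 higher with siRNA. In 3723 genes (30.0%) both siRNA libraries lay below both controls, and in 1065 (8.60%) both lay above, where chance gives 16.7% each. Between-library scaling brought the unadjusted count under 620: 472 with TPM (336 lower, 136 higher), 460 with median-of-ratios scaling (290 and 170), 462 with quantile normalization (255 and 207) and 513 with cyclic loess (252 and 261). Genes with both siRNA libraries below and above both controls then numbered 2634 and 1645, 2365 and 2087, 2322 and 2046, and 2290 and 2176. The unadjusted count was also under 620 with a pseudocount of 0.1 (603), without the trend (609) and without control replicates 1 and 2 (149 and 156). With no filter it was 844, where chance gives 1126. The median log2 difference of all tested genes was -0.39, and it was -0.30 in siRNA replicate 1 and -0.57 in siRNA replicate 2. Without siRNA replicate 1, which sets siRNA replicate 2 alone against the controls, 1477 genes passed (278 higher, 1199 lower) and 4146 had an unadjusted p under 0.05. Without siRNA replicate 2, 0 genes passed in limma and 1008 had an unadjusted p under 0.05.

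None of the genes named here passed the test with both siRNA libraries. Among those with the smallest unadjusted p and lower values, Psmb5, a catalytic subunit of the proteasome, stood at 97.1 and 137 FPKM in controls and 19.7 and 6.01 FPKM with siRNA. Mrpl28, a protein of the large mitochondrial ribosomal subunit, stood at 83.7 and 99.1 FPKM in controls and 17.9 and 8.13 FPKM with siRNA. Tmed5, a cargo receptor of the early secretory pathway, stood at 473 and 401 FPKM against 97.0 and 43.5 FPKM, and Zmat5 at 360 and 316 FPKM against 64.9 and 26.6 FPKM. Pop5, Abhd11 and Ppp4c had log2 fold changes of -3.23, -4.03 and -2.95. Snord11, Mir1982 and Eif3s6-ps2 were listed at 0 in both siRNA libraries and at 19.6 and 21.3 FPKM, 12.4 and 28.1 FPKM, and 12.0 and 19.3 FPKM in the controls. l7Rn6 stood at 34.1 and 10.2 FPKM in the controls and near 0 with siRNA.

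Among genes with higher values, Pou2f1, a POU-domain transcription factor, stood at 0.238 and 0.109 FPKM in controls and 7.19 and 22.4 FPKM with siRNA. Zbp1, a sensor of nucleic acids, stood at 0.354 and 0 FPKM in controls, with a log2 fold change of 3.40 and higher values in both siRNA libraries. Sqstm1, an autophagy receptor, stood at 0.295 and 0 FPKM against 4.68 and 11.4 FPKM. Fbxo18 stood at 3.59 and 3.03 FPKM against 16.6 and 107 FPKM, and Cntrob at 0.887 and 0 FPKM against 8.41 and 133 FPKM. Clcn7, Apeh and Mir3968 had log2 fold changes of 2.79, 3.47 and 3.18. Irx2, Purg, n-R5s153 and Snord47 were listed at 0 in both controls, and at 4.24 and 60.2 FPKM, 2.58 and 10.2 FPKM, 9.53 and 49.9 FPKM, and 146 and 99.6 FPKM with siRNA. Snord47, Snord11, Mir1982, Mir3968 and n-R5s153 are shorter than a usual library fragment, so their FPKM values are uncertain.

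Of the 25 gene lists 6 passed in limma's camera, all lower with siRNA: the proteasome, mitochondrial and cytosolic ribosomal proteins, antioxidant genes, complex I, and complex IV and V. Each call was lost with an estimated correlation (adjusted p = 0.902 for each of the 6). That version rests on 2 residual degrees of freedom and has little power, so the loss alone does not decide. The estimated correlations were 0.040, 0.156 and 0.044 for the proteasome and mitochondrial and cytosolic ribosomal proteins. They were 0.078, 0.086 and 0.161 for antioxidant genes, complex I, and complex IV and V. Each exceeded the preset of 0.01, so the calls at the preset may be too lenient. Proteasome subunits had a median log2 difference of -0.83 (adjusted p = 0.0167), and 22 of 36 members lay below both controls in both siRNA libraries. Psma7 stood at 241 and 202 FPKM in controls and 75.4 and 30.1 FPKM with siRNA, and Psmc2 and Psmg4 had log2 fold changes of -2.34 and -2.31. Mitochondrial ribosomal proteins had a median of -0.70 (adjusted p = 0.0167), with 34 of 74 members below, among them Mrps10, Mrpl27 and Mrpl34 at -3.38, -3.67 and -1.56. Cytosolic ribosomal proteins had a median of -0.74 (adjusted p = 0.0376), with 41 of 76 members below, among them Fau, Rpl19 and Rpl35 at -2.28, -2.31 and -1.45. Ribosomal protein genes have near-identical processed copies, so their values are uncertain. The proteasome's offset from all genes was -0.44, and it was -0.18, -0.48, -0.31 and -0.66 without control replicates 1 and 2 and siRNA replicates 1 and 2 (adjusted p = 0.280, 0.0257, 0.279 and 9.5e-07). That of mitochondrial ribosomal proteins was -0.31, and -0.26, -0.54, -0.31 and -0.10 without control replicates 1 and 2 and siRNA replicates 1 and 2 (adjusted p = 0.280, 0.0309, 0.0140 and 0.0843). That of cytosolic ribosomal proteins was -0.35, and -0.25, -0.36, 9.9e-05 and -0.60 without control replicates 1 and 2 and siRNA replicates 1 and 2 (adjusted p = 0.360, 0.142, 0.609 and 1.4e-07). Over 21 alternatives the adjusted p of these 3 lists ranged from 9.5e-07 to 0.280, 6.3e-05 to 0.280 and 1.4e-07 to 0.771.

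Antioxidant genes had a median log2 difference of -0.92 (adjusted p = 0.0295), with 13 of 24 members below both controls in both siRNA libraries. Gpx1 and Gpx4, which reduce peroxides, stood at -1.51 and -2.04, and Gsto1 and Gclm at -3.04 and -1.45. Complex I subunits had a median of -0.85 (adjusted p = 0.0444), with 18 of 36 members below. Ndufs8 stood at 178 and 129 FPKM in controls and 51.6 and 0.572 FPKM with siRNA, and Ndufb7, Ndufa12 and Ndufs3 had log2 fold changes of -2.59, -1.87 and -2.41. Complex IV and V subunits had a median of -0.63 (adjusted p = 0.0376), with 17 of 26 members below, among them Atp5g1, Cox6a1, Cox5a and Atp5j at -2.01, -1.48, -1.56 and -1.31. The offset of antioxidant genes was -0.53, and it was -0.60, -0.50, -0.85 and -0.17 without control replicates 1 and 2 and siRNA replicates 1 and 2 (adjusted p = 0.238, 0.142, 0.0391 and 0.0715). That of complex I was -0.46, and -0.47, -0.17, -0.38 and -0.18 without the same libraries (adjusted p = 0.238, 0.250, 0.0391 and 0.154). That of complex IV and V was -0.25, and -0.32, -0.37, -0.16 and -0.28 without them (adjusted p = 0.280, 0.173, 0.0391 and 0.0094). Over 21 alternatives the adjusted p of these 3 lists ranged from 0.0036 to 0.238, 0.00087 to 0.542 and 0.00092 to 0.704. In none of the 25 lists did a member pass over all genes, and 0 members passed adjusted over the list alone in each of them. None of the 6 lists passed with a filter at 5 FPKM, after rescaling to TPM, median-of-ratios scaling, quantile normalization, cyclic loess or the length correction, or against random lists matched on expression. Among those random lists the proteasome and mitochondrial and cytosolic ribosomal proteins stood at percentiles 11.54, 7.02 and 16.77. Antioxidant genes, complex I, and complex IV and V stood at 5.56, 6.17 and 64.85. Matched on expression and length, the lists in this order stood at 27.11, 29.08, 81.94, 8.03, 43.52 and 75.93. Only antioxidant genes then stayed near the low end.

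Complex III, which Uqcc3 helps to assemble, did not pass as a list (median -0.29, limma camera adjusted p = 0.509). Its median lay 0.098 above the median of all genes and its mean -0.29 from the mean of all genes, with camera's direction down. Uqcrc1, a core subunit, stood at 25.8 and 21.6 FPKM in controls and 1.87 and 1.01 FPKM with siRNA, and Uqcr10 at 958 and 616 FPKM against 300.2 and 183 FPKM. Cyc1 and the assembly factor Uqcc2 had log2 fold changes of -2.12 and -1.66. The mitochondrially encoded mRNAs did not pass with both siRNA libraries (median -0.53, limma camera adjusted p = 0.997). Their median log2 difference was 0.51 in siRNA replicate 1 and -1.54 in siRNA replicate 2, and 0.64 between the 2 controls. mt-Cytb stood at 44269 and 47540.2 FPKM in the controls. Its log2 difference from the controls was 0.33 in siRNA replicate 1 and -3.57 in siRNA replicate 2. mt-Atp8, mt-Nd5 and mt-Nd6 had log2 fold changes of -2.94, -0.53 and 0.52.

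Lists tied to genome activation did not pass with both siRNA libraries in limma's camera, with 1 exception when low values were not filtered. The 2-cell-specific genes had a median of -0.48 (adjusted p = 0.749), with 18 of 54 members below both controls in both siRNA libraries and 4 above. Of all tested genes 30.0% lay below and 8.60% above, with a median of -0.39, so this list was close to all genes. Obox6 stood at 600.3 and 560 FPKM in controls and 285 and 138 FPKM with siRNA. Usp17lb, Usp17le and Obox4-ps35 had log2 fold changes of -2.17, -2.30 and -4.09. These are multicopy families whose members share sequence, so single values are uncertain. Cleavage-stage and pluripotency transcription factors had a median of -0.34 (adjusted p = 0.509), with Nfya, Tfcp2l1, Gabpa and Yap1 at -2.77, -3.13, -1.16 and 1.52. Maternal oocyte transcripts had a median of -0.38 (adjusted p = 0.688), with Nlrp4f, Tle6, Tcl1b5 and Zp3 at 2.10, 2.66, -1.69 and -2.07. Ribosome biogenesis factors had a median of -0.60 (adjusted p = 0.261), with 45 of 105 members below, among them Nhp2, Polr1e, Imp4 and Nop16 at -1.90, -2.07, -2.20 and -2.25. With no filter on low values this list passed, lower (offset -0.50, adjusted p = 0.00097, and 0.604 with an estimated correlation). Spliceosome core factors had a median of -0.27 (adjusted p = 0.997), with Snrpc, Srsf7, Plrg1 and Snrnp40 at -1.67, -1.53, -2.68 and -1.70.

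The siRNA libraries differed from each other in these lists. Against the median of all genes, maternal oocyte transcripts lay at 0.47 in siRNA replicate 1 and -0.67 in siRNA replicate 2. Ribosome biogenesis factors lay at -0.64 and 0.45, spliceosome core factors at -0.60 and 0.73, and mitochondrial proteostasis genes at -0.76 and 0.40. In 16 of the 25 lists the 2 siRNA libraries lay on opposite sides of the median of all genes. The difference between the 2 libraries was not tested. With siRNA replicate 1 alone 12 lists passed in limma's camera, and with siRNA replicate 2 alone 5 lists passed. With an estimated correlation 0 lists passed in either (smallest adjusted p = 0.607 and 0.938).

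**Figure D2:**
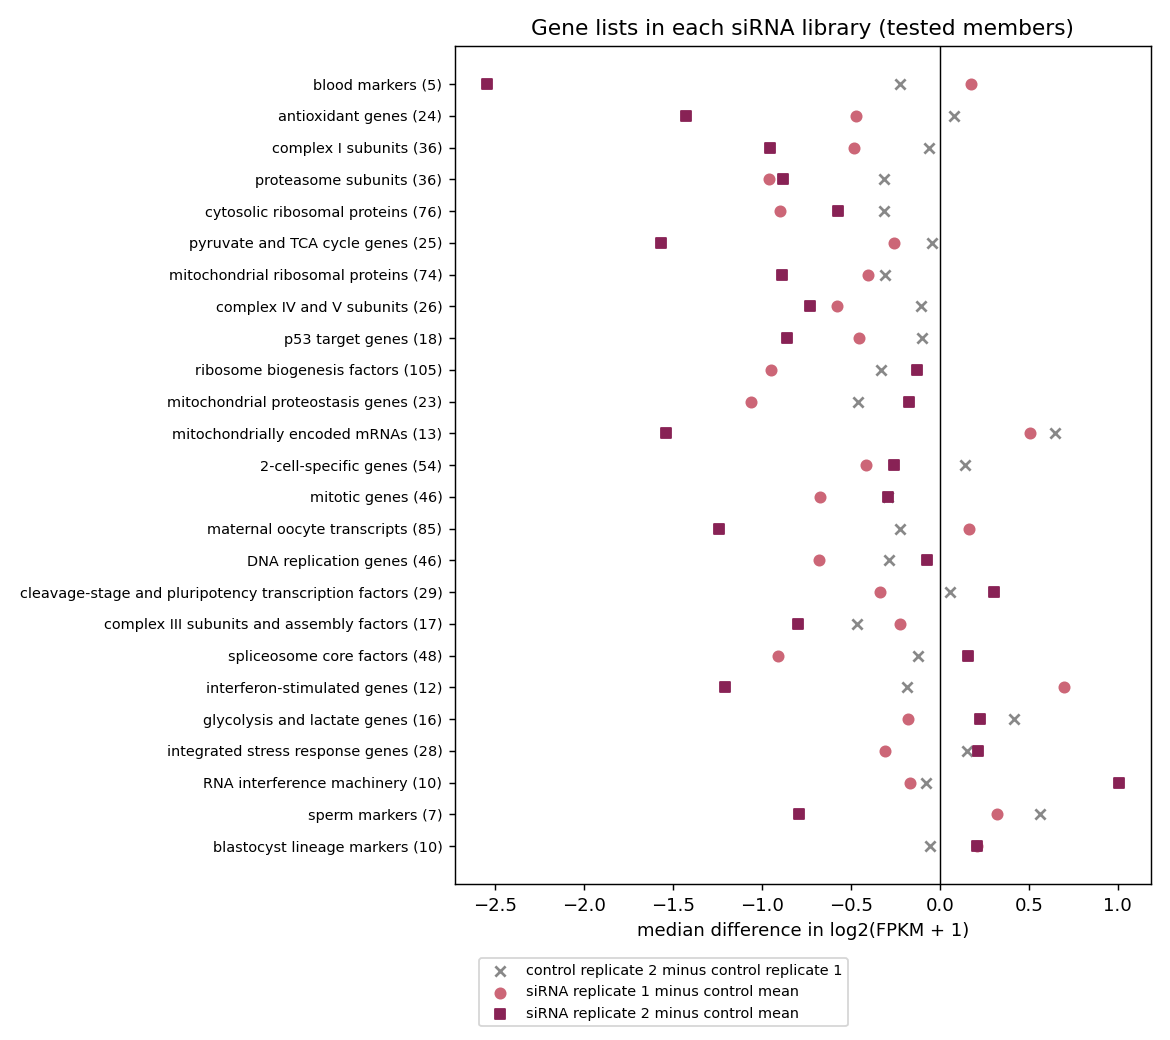
Median difference in log2(FPKM + 1) of each gene list, with 1 row per list and its number of tested members in brackets. Circles and squares are siRNA replicates 1 and 2 against the control mean, and crosses are the difference between the 2 controls, which reaches 0.64 for the mitochondrially encoded mRNAs.

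Lists of metabolism, stress and division did not pass with both siRNA libraries in limma's camera, with 2 exceptions when low values were not filtered. Pyruvate and TCA cycle genes had a median of -0.74 (adjusted p = 0.351), with Mdh2, Mdh1, Idh3g and Ogdh at -2.02, -1.96, -1.93 and -1.27. Glycolysis and lactate genes had a median of -0.027 (adjusted p = 0.261), with Eno1, Slc2a1, Pfkl and Hk2 at -1.44, 1.59, -1.28 and 2.08. Mitochondrial proteostasis genes had a median of -0.54 (adjusted p = 0.503), with Timm17a, Timm23, Trap1 and Htra2 at -2.80, -2.63, -2.58 and -2.37. Genes of the integrated stress response had a median of -0.0040 (adjusted p = 0.509), with Eprs, Psph, Cars and Slc3a2 at -2.68, -2.69, -1.86 and -1.15. The p53 targets had a median of -0.63 (adjusted p = 0.915), with Psrc1, Tigar, Cdkn1a and Ccng1 at -2.16, -1.19, -1.60 and 1.56. Mitotic genes had a median of -0.44 (adjusted p = 0.503), with Bub3, Ccnb1, Racgap1 and Cenpa at -2.09, -1.94, -1.66 and -1.33. DNA replication genes had a median of -0.34 (adjusted p = 0.997), with Rfc5, Prim2, Rrm1 and Gins1 at -2.34, -2.21, -2.21 and -2.20. Interferon-stimulated genes had a median of -0.26 (adjusted p = 0.509), with Irf7, Ifi35 and Irf1 at -1.85, -1.87 and 2.08. With no filter on low values mitotic genes passed, lower, and interferon-stimulated genes passed, higher (offsets -0.38 and 0.12, adjusted p = 0.0159 and 0.0382, and 0.604 and 0.592 with an estimated correlation). The RNA interference machinery had a median of 0.25 (adjusted p = 0.416), with Ago3, Tnrc6c, Drosha and Ago2 at -2.20, 1.31, 0.87 and 0.51.

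Markers of other cell types did not pass with both siRNA libraries in limma's camera, and sperm markers passed with siRNA replicate 1 alone (offset 0.62, adjusted p = 0.0444, and 0.607 with an estimated correlation). Blood markers had a median of -1.19 over 5 members (adjusted p = 0.997). Their mean lay -0.18 from the mean of all genes, which differed in sign from camera's upward direction. Hba-a1 stood at 9.26 and 18.8 FPKM in controls and 9.75 and 0 FPKM with siRNA, and Hba-a2, Cd52 and Cd74 had log2 fold changes of -1.92, 1.39 and -1.19. Sperm markers had a median of 0.30 over 7 members (adjusted p = 0.509), with Pgk2, Tssk6, Ldhc and Tnp1 at -1.53, -0.49, 0.35 and 0.50. Blastocyst lineage markers had a median of 0.39 over 10 members (adjusted p = 0.236), with Eomes, Fgf4, Aqp3 and Lgals1 at 1.67, -1.36, 1.08 and -2.09. Of 26 cumulus and granulosa cell markers 2 were tested, too few for a list test. With no filter on low values 18 were tested and passed, higher with siRNA (offset 0.22, adjusted p = 0.0036, and 0.592 with an estimated correlation). Of these 18, 15 lay under 1 FPKM in all 4 libraries. Tnfaip6 stood at 2.91, 14.1, 3.60 and 0.602 FPKM in control replicates 1 and 2 and siRNA replicates 1 and 2, and Hsd17b1 at 2.37, 1.21, 4.61 and 0.197 FPKM.

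Values of siRNA replicate 2 followed transcript length. Genes of the shortest of 10 length classes (median length 425 nucleotides) had a median log2 difference from the controls of -1.51 in siRNA replicate 2 and -0.24 in siRNA replicate 1. Genes of the longest class had 0.36 and -0.18. Between the 2 controls the same medians were 0.040 and -0.23.

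**Figure D3:**
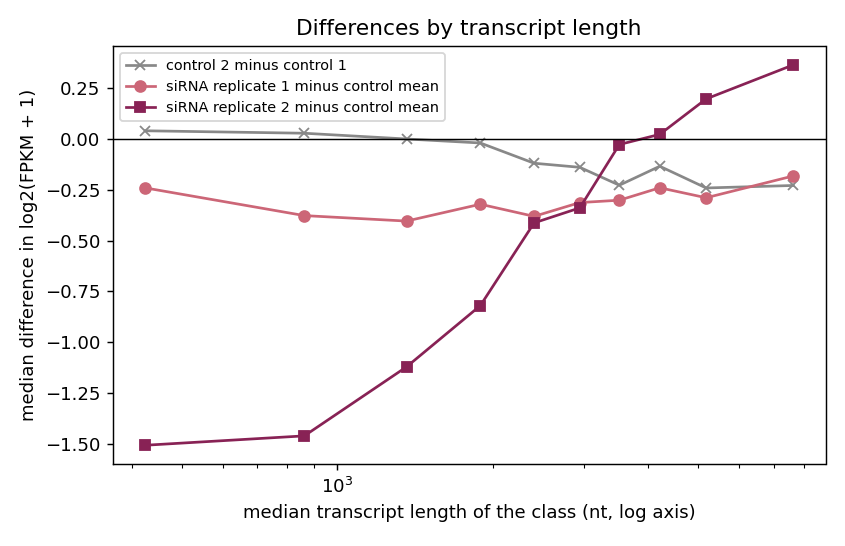
Median difference in log2(FPKM + 1) for 10 classes of genes by transcript length, with length in nucleotides on a log axis. The line of siRNA replicate 2 runs from -1.51 in the shortest class to 0.36 in the longest, and that of siRNA replicate 1 from -0.24 to -0.18.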

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

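The alternatives with library weights, with length and GC content, with 10 implied fragments, with siRNA replicate 1 alone after correction, and with random lists matched on expression and length were chosen after seeing the data. Uqcc3 stayed lower in all 21 alternatives (log2 fold change -3.23 to -2.34, limma adjusted p 0.0238 to 1.00), and passed only without siRNA replicate 1 (-3.09), where the lone library of a group is assumed to vary like the other group. The count of genes past the threshold stayed at 0 in 18 of 21 alternatives. It was 1 with the replicate block, 4 with siRNA replicate 1 against controls after the length and GC correction, and 1477 without siRNA replicate 1 (0 to 1477 over the libraries left out). The gene of the block was Snord47, and the 4 genes, named after their values were seen, were Snord47, Ino80c, Gm22133 and Snora47. The cause was not tested. The block used numbers in the submitters' file names, which the labels do not give. Deviations of libraries with the same number correlated at 0.058 across genes, which gives no sign of pairing. As siRNA replicate 2, which stands apart, enters this value, a pairing is not excluded. Library weights came out as 1.99 for both controls and 0.503 for both siRNA libraries. With 2 libraries per group they cannot tell replicates apart.

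The number of lists past the threshold was 6. It was 10 of 26 with no filter on low values, with ribosome biogenesis factors, mitotic genes, interferon-stimulated genes and cumulus and granulosa cell markers added, 3 in limma without the trend and 2 with the replicate block. It was 12 with siRNA replicate 1 against controls after the length and GC correction. It was 0 with an estimated correlation, 0 with mixed fry and 1 with one-directional fry (p53 target genes). It was 0 with random lists matched on expression and 0 with those matched on expression and length. It was 0 with a filter at 5 FPKM, TPM, median-of-ratios scaling, quantile normalization, cyclic loess, the length correction and the length and GC correction. It ran from 0 to 12 over the libraries left out (0 and 2 without control replicates 1 and 2, 5 and 12 without siRNA replicates 1 and 2). The median log2 of all genes was -0.39 and moved to -0.080 with TPM, -0.055 with median-of-ratios scaling, 0.012 with quantile normalization and 0.034 with cyclic loess.

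Of the comparisons of named genes 2423 kept their direction and side of the threshold, 72 came to pass it and 21 reversed. Of those of lists 373 kept both, 63 lost the call, 16 gained one and 72 reversed. The values that follow are offsets of lists from all genes, or log2 fold changes of genes, where the direction reversed, and the cause was not tested. With a pseudocount of 0.1 they were 0.059 for mitotic, -0.51 for interferon-stimulated and 0.0061 for 2-cell-specific genes. With a pseudocount of 5 they were -0.085 for complex III, -0.038 for cleavage-stage factors, -0.13 for maternal transcripts, -0.025 for the spliceosome and -0.072 for DNA replication. With no filter they were -0.35 for complex III, -0.25 for cleavage-stage factors, -0.28 for maternal transcripts, -0.20 for the spliceosome, 0.19 for blood markers and -0.25 for DNA replication. With a filter at 5 FPKM they were 0.0081 for mitotic, 0.067 for mitochondrial proteostasis and 0.15 for 2-cell-specific genes and 0.0093 for mitochondrially encoded mRNAs. With TPM they were 0.064 for mitotic, -0.18 for interferon-stimulated and 0.010 for 2-cell-specific genes. Median-of-ratios scaling gave 0.026 for mitotic genes, and quantile normalization 0.012 for mitotic genes and -0.0061 for DNA replication. Cyclic loess gave 0.076 for complex IV and V, 0.14 for mitotic and 0.079 for 2-cell-specific genes, 0.38 for mitochondrially encoded mRNAs and 0.42 for mt-Nd5. The length correction gave 0.0042 for complex IV and V, -0.071 for interferon-stimulated genes, -0.0060 for cleavage-stage factors, 0.063 for 2-cell-specific genes, 0.26 for mitochondrially encoded mRNAs, -0.012 for the spliceosome and -0.032 for DNA replication. With length and GC content it gave 0.054 for complex IV and V, -0.081 for interferon-stimulated genes, -0.12 for cleavage-stage factors, 0.10 for 2-cell-specific genes, 0.31 for mitochondrially encoded mRNAs and -0.024 for DNA replication. With siRNA replicate 1 against controls after that correction, lists stood at 0.11 for pyruvate and TCA cycle genes, -0.014 for cleavage-stage factors, 0.55 for mitochondrially encoded mRNAs, -0.58 for the spliceosome, 0.62 for blood markers and -0.38 for DNA replication. Genes there stood at 0.20 for mt-Cytb, 0.23 for mt-Nd5, -0.24 for Hk2, -0.095 for Drosha, -0.21 for Ago2, 0.072 for Pgk2, 0.32 for Cd74 and 0.25 for Lgals1.

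Over the 4 fits that leave out 1 library, the Uqcc3 log2 fold change ranged from -3.23 to -2.71. The offsets of lists that reversed ranged from -0.60 to 9.9e-05 for cytosolic ribosomal proteins, -0.64 to 0.45 for ribosome biogenesis, -0.37 to 0.28 for mitotic genes, -0.67 to 0.47 for maternal transcripts, -0.99 to 0.11 for pyruvate and TCA cycle genes, -0.22 to 0.079 for complex III, -0.14 to 0.32 for 2-cell-specific genes and -0.96 to 0.81 for mitochondrially encoded mRNAs. They ranged from -0.38 to 0.50 for DNA replication, -0.76 to 0.40 for mitochondrial proteostasis, -0.63 to 1.00 for interferon-stimulated genes, -0.22 to 0.62 for sperm markers, -0.035 to 0.88 for cleavage-stage factors, -0.0013 to 0.79 for the integrated stress response, -0.60 to 0.73 for the spliceosome and -1.97 to 0.48 for blood markers. Genes ranged from -0.79 to 1.80 for Tnp1, -0.16 to 2.94 for Cd52, -0.093 to 1.13 for mt-Nd6, -3.57 to 0.33 for mt-Cytb, -1.48 to 0.42 for mt-Nd5, -0.28 to 4.44 for Hk2, -0.15 to 1.89 for Drosha, -0.15 to 1.16 for Ago2, -3.09 to 0.036 for Pgk2, -2.55 to 0.17 for Cd74 and -4.32 to 0.13 for Lgals1. Depth was 11500000 to 18700000 implied fragments per library.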

Other observations

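The tests of depth, of length classes, of lists on the same side in both siRNA libraries, with the length and GC correction, with 200 implied fragments, with missing transcripts and with an estimated correlation in 3 libraries were chosen after the results were seen. So was the use of the length correction, cyclic loess and matched random lists to weigh explanations. The marks for missing transcripts, and for a length trend in the lists lower with both siRNA libraries, were made stricter after their values were seen. Both had been met before that. The mark for lower values of abundant genes was also changed after its values were seen. With siRNA replicate 1 alone against the controls, the lists past the threshold in limma's camera that lay higher than all genes were maternal oocyte transcripts (offset 0.47), mitochondrially encoded mRNAs (0.81), interferon-stimulated genes (1.00) and sperm markers (0.62). Those that lay lower were ribosome biogenesis factors (-0.64), cytosolic ribosomal proteins (-0.60), the proteasome (-0.66), complex IV and V (-0.28), the spliceosome (-0.60), mitochondrial proteostasis (-0.76), mitotic genes (-0.37) and DNA replication (-0.38). These calls compare 1 library with 2, and with an estimated correlation the smallest adjusted p was 0.607. Against random lists matched on expression, 8 lists passed. With siRNA replicate 2 alone, the 5 lists past the threshold were mitochondrial ribosomal proteins, antioxidant genes, complex IV and V, complex I and mitochondrially encoded mRNAs, and 0 passed against matched random lists.

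The first pattern is that siRNA replicate 2 stands apart from the other 3 libraries. Lower depth is argued against, since it held 1.02 times the implied fragments of siRNA replicate 1, which correlated with the controls at up to 0.872. A stronger response to the same siRNA is argued against as the whole cause, since most lists changed side. Uqcc3 stood at 23.7 and 19.8 FPKM, but its longest transcript has only 821 nucleotides. Genes of the length class with a median of 863.5 nucleotides had median log2 differences from the controls of -0.38 and -1.46 in siRNA replicates 1 and 2. The Uqcc3 values alone therefore do not show an equal response. Of the 12 lists past the threshold with siRNA replicate 1, 2 lay on the same side in siRNA replicate 2. These sides were not corrected for length, and cytosolic ribosomal proteins counted as opposite at 9.9e-05. Against random lists matched on expression and length, maternal transcripts stood at percentiles 100 and 1.27 in siRNA replicates 1 and 2, and the spliceosome at 0 and 99.43. The proteasome (0.33 and 44.78), mitotic genes (6.28 and 45.6) and sperm markers (90.36 and 56.75) stayed on the same side of the middle. A loss of transcripts before amplification without regard to gene class or length is argued against as the whole cause, since medians of the longest and shortest of 10 length classes differed by 1.87, and mt-Cytb, at 44269 and 47540.2 FPKM in the controls, lay at -3.57. It stays open for 112 of 2475 abundant genes that lay under 1 FPKM (39 listed at 0, genes marked as failed left out). Of 19 lists 0 passed a test of a different share, with at most 2.31 such genes expected in any list (Fisher's exact test, smallest adjusted p = 1). Among the 377 abundant list members 7 lay under 1 FPKM, a lower share than the 4.53% of all abundant genes. That lower share goes against a loss without regard to gene class, but the difference was not tested.

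The second pattern is the 6 lists that passed with both siRNA libraries, of which 0, 2, 4 and 3 passed without control replicates 1 and 2 and siRNA replicates 1 and 2. Lower values of abundant genes in general stay open. Against random lists matched on expression the 6 lists stood at percentiles 5.56 to 64.85, and at 8.03 to 81.94 when matched on length too. Of the 6 lists 0 passed against these or after cyclic loess on abundance, but after cyclic loess the offset of 2 of the 6 was less than 0.5 times that before. A trend with transcript length stays open too: after its correction this held for 3 of the 6, and the median of the 6 offsets, -0.40 before, was -0.16, against -0.28 after cyclic loess. After cyclic loess complex I went from -0.46 to -0.40 (interquartile range 1.25 and 1.21) and the proteasome from -0.44 to -0.34 (0.7511 and 0.9003). Antioxidant genes went from -0.53 to -0.40 (0.965 and 0.975) and mitochondrial ribosomal proteins from -0.31 to -0.22 (1.23 and 1.19). These calls lost after cyclic loess are weak support for abundance. After the length correction the last 2 stood at -0.43 and -0.25 (0.851 and 1.02), weak support for length. Complex I and the proteasome then stood at -0.030 and -0.24 (1.13 and 0.993), so for complex I the offset was nearly gone. A response to the siRNA cannot be told apart from a difference between batches. With an estimated correlation 0 of the 6 lists passed, but at 2 residual degrees of freedom that test has little power and does not decide it.

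The third pattern is that of siRNA replicate 1, with maternal transcripts higher and ribosome biogenesis lower. A trend with transcript length or GC content is argued against, since all 12 lists past the threshold stayed past it on the same side after that correction (12 of 12). Among 4373 genes with at least 200 implied fragments in both controls, lower depth is argued against for maternal transcripts and ribosome biogenesis, set apart after the count of 5 below was seen (2 of 2 passed on the same side, offsets 0.56 and -0.48), and the offsets of mitochondrially encoded mRNAs, the proteasome and cytosolic ribosomal proteins (1.32, -0.45 and -0.32) go against it too. Lower depth stays open for the other 7, since 5 of the 12 passed there. Fewer than 6 was its mark as first written, so that mark was met. A further demand, each offset less than 0.5 times that among all genes, was added after the values were seen. Calls were lost with fewer members, and 10 of the 10 lists with enough members kept their side (2 at less than 0.5 times the offset, mitochondrial proteostasis at -0.58, the spliceosome at -0.37). In siRNA replicate 2, of like depth but apart from the others, 10 of the 12 lay on the other side. Among these, cytosolic ribosomal proteins (9.9e-05) and interferon-stimulated genes had the same camera direction in both siRNA libraries. Developmental delay of these embryos is a hypothesis that cannot be told apart from other differences of this library: the 2-cell-specific genes stood at percentile 61.04 of random lists matched on expression, a delay can put them on either side, and 1 library shows the pattern.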
